A study of Mus musculus with 6 samples.

How the data were processed

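RNA was measured by RNA sequencing in cortex of wild-type mice, with 3 libraries from cortex given AAV-GFP-GA and 3 from cortex given AAV-GFP, all labelled with a time of 5 months. AAV is an adeno-associated viral vector that carries a gene into cells. GFP, green fluorescent protein, served as the control cargo, and GFP-GA is its fusion with poly-GA, a chain of repeated glycine and alanine. Poly-GA is 1 of the dipeptide repeat proteins made from the expanded repeat in C9orf72, a common genetic cause of amyotrophic lateral sclerosis and frontotemporal dementia. RNA was extracted with Trizol and the libraries followed the standard protocol of the sequencing provider, BGI, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.12 and the mouse genome build mm10, without the role or order of the tools. The annotation, the strand setting and any filter on reads are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, may have been assigned to either partner.

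The deposited table holds 1 column per library of expected counts per gene, the estimated number of reads a gene received, with no scaling to depth. The unit was read from the values: the column names call them read counts, 7.32% to 7.81% of the entries in a library were not whole, and the columns had different totals, as RSEM expected counts do. RSEM shares reads that match several genes among them, so the values of gene families with near-identical members rest on that estimate. The table had 18283 gene rows and 1 row that named no gene, which was left out of all totals and tests. Symbols that a spreadsheet had turned into dates were restored from the gene identifiers in all 25 cases. Of the 18283 gene identifiers, 18162 were found in the RefSeq gene table used for coordinates, whose assembly, GRCm38.p6, is the build also called mm10. Coordinates are 1-based.

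Total expected counts were 17548304, 17576017 and 17493438 in AAV-GFP-GA replicates 1, 2 and 3, and 16748754, 16761637 and 17237278 in AAV-GFP replicates 1, 2 and 3. The 10 genes with most reads took between 3.18% and 3.34% of a library. No columns were identical, and replicates of 1 group differed by more than sampling noise, with a chi-square per degree of freedom between 3.17 and 10.2 over pairs. All 6 libraries were therefore kept as separate samples.

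Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 14324 genes, and libraries were scaled by the trimmed mean of M values, with factors between 0.991 and 1.01. The comparison used edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with all 6 libraries, no covariate, and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Log2 fold changes are AAV-GFP-GA over AAV-GFP and are given with their standard error, written as ± SE, and 95% confidence intervals where useful. CPM values, which relate a gene's reads to the size of its library, were computed from the rounded counts with the scaled library sizes and are given as mean ± SD over 3 libraries. The typical spread between replicates, as the common biological coefficient of variation, was 7.92%.

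Gene lists of cell types, immune pathways, stress pathways and signs of RNA quality, 41 in all, were written from textbook markers before the data were examined, as were the groups, the tests and all but the last 2 alternatives. A list was tested where at least 4 members passed the filter, which held for 37 lists. Each list was tested with camera from limma 3.58.1, which asks whether its genes move further than other genes, with the preset correlation between genes of 0.01 and again with a correlation estimated from the data. It was also tested with fry, which asks whether its genes move, on balance, in 1 direction, or in either direction in its mixed form. List p-values were adjusted over the 37 lists. The rule for named genes was also set beforehand. It named Trem2, Tyrobp, Nlrp3, Pycard, Casp1, Il1b, Gfap, Aif1 and Cd68 always. It further named the 12 higher and 8 lower genes with the largest change among those past the threshold whose groups did not overlap, predicted genes left out. Of each list it named up to 4 members past the threshold or, where there were none, the 2 members with the highest expression. A few genes that the rule names are not reported here.

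The gene tests were tested on simulated data drawn from the real means and library sizes for 14236 genes, of which 200 were changed by a known fold. In this simulated comparison of AAV-GFP-GA with AAV-GFP, edgeR recovered 77.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 97.0% of those changed 4-fold, and called 12 unchanged genes. The changed genes were drawn only from genes above a minimum number of reads. With 200 changed genes edgeR made 192 calls, so the adjusted threshold was easier to pass than with the 3 calls in the real data. The shares recovered therefore do not give the power of the real comparison. A simulated list shifted by 0.5 on the log2 scale passed with camera under the preset and the estimated correlation and with fry, and none of the 40 unchanged lists did. The simulated genes were drawn independently of each other. In the real lists the estimated correlation between genes ranged from -0.04 for inhibitory neurons to 0.999 for sex-linked genes. The simulation therefore cannot show how often camera with the preset correlation calls an unchanged list whose genes move together.

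The processing was also varied in these ways: the Wald test of DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter on low counts, a stricter filter with a mean of at least 10 reads in each group, limma sample weights, the replicate number as a block, and each library left out in turn. The last 2 were added after the data had been seen, and put a term in the fit for the set of libraries with reads of intestinal genes, and a term for the presence of Y-linked reads. The labels do not say whether the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical.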

Results

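The data were gene-level read counts from mouse cortex that had received AAV-GFP-GA, which expresses the poly-GA dipeptide repeat protein fused to GFP, or AAV-GFP, which expresses GFP alone. Each group had 3 libraries, with 16748754 to 17576017 expected counts per library over 18283 genes, of which 14324 were expressed highly enough to be tested. The title of the study places poly-GA clearance under TREM2, a receptor of microglia, and the NLRP3 inflammasome, the caspase-1 activating complex that releases interleukin-1β. The comparison asks which transcripts differ in cortex that expresses poly-GA.

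Cortex with poly-GA had higher levels of Nes, Klf4 and Klf2 than cortex with GFP alone. Nes, which encodes the intermediate filament nestin, rose 2.40-fold, from 10.05 ± 1.72 to 24.1 ± 0.368 CPM (SD, n = 3 per group). Klf4 and Klf2 encode Krüppel-like transcription factors that are active in endothelium, the cells lining blood vessels. Klf4 rose 2.26-fold, from 8.65 ± 0.656 to 19.6 ± 1.98 CPM, and Klf2 rose 1.87-fold, from 12.99 ± 0.749 to 24.3 ± 1.90 CPM (SD, n = 3 per group).

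Nes (Entrez gene 18008, chromosome 3, 87971093 to 87980451, mm10) had 424, 420 and 422 reads in the AAV-GFP-GA libraries and 198, 165 and 146 in the AAV-GFP libraries. Its log2 fold change was 1.26 ± 0.11 (SE), with a 95% interval from 2.01-fold to 2.86-fold. Klf4 (Entrez gene 16600, chromosome 4, 55527137 to 55532475) had 316, 387 and 326 reads against 157, 141 and 141, a log2 fold change of 1.18 ± 0.11. Klf2 (Entrez gene 16598, chromosome 8, 72319062 to 72321654) had 453, 439 and 385 reads against 210, 210 and 240, a log2 fold change of 0.90 ± 0.09. The adjusted p by edgeR's quasi-likelihood test was 0.00299 for Nes and Klf4 and 0.00588 for Klf2. For each of these genes all 3 AAV-GFP-GA values lay above all 3 AAV-GFP values. No gene was called lower by edgeR, where 494 genes were lower at an unadjusted p under 0.05. DESeq2 called 9 genes higher and 1 lower, and limma-voom called 3 higher and 0 lower. DESeq2 added Apold1, Flt1, Slc2a1, Akap12, Atf3 and Gvin1 to the higher genes and called the predicted gene Gm14434 lower. Klf2 did not pass when AAV-GFP-GA replicate 1, AAV-GFP-GA replicate 2 or AAV-GFP replicate 2 was left out, with adjusted p-values of 0.0718, 0.0522 and 0.0648, in a range from 1.28e-08 to 0.0718 over all alternatives. Without AAV-GFP replicate 3 the count of changed genes went from 3 to 72, with 38 higher and 34 lower.

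**Figure D1:**
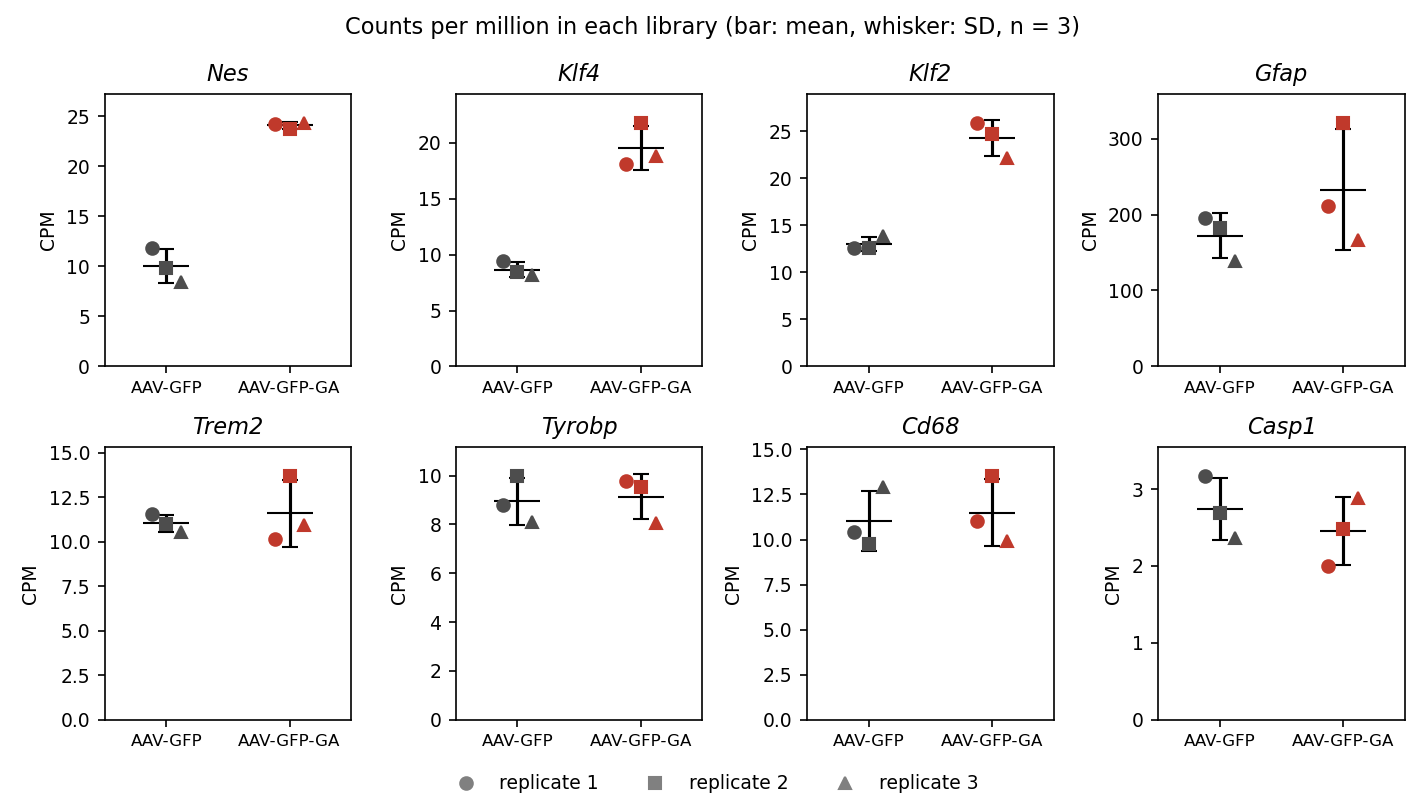
CPM of 8 genes in each library, with AAV-GFP in grey and AAV-GFP-GA in red, the replicate shown by the shape of the point, the mean as a horizontal bar and the SD as a whisker (n = 3 per group). The AAV-GFP-GA libraries lie above all AAV-GFP libraries for Nes, Klf4 and Klf2, and the groups overlap for Gfap, Trem2, Tyrobp, Cd68 and Casp1.

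The 6 genes ranked next by p did not pass the threshold in edgeR. They were singled out after their values were seen. Apold1, an early response gene of endothelium, was at 21.1 ± 4.18 against 11.0 ± 0.195 CPM (SD, n = 3 per group), with an adjusted p of 0.109 by edgeR. Flt1, a receptor for vascular endothelial growth factor, had a log2 fold change of 0.41 ± 0.08 and an adjusted p of 0.444 by edgeR. Atf3, a stress-induced transcription factor, had a log2 fold change of 1.57 ± 0.30 and an adjusted p of 0.475 by edgeR, and Akap12, Epha2 and Gvin1 had log2 fold changes of 0.46 ± 0.08, 1.42 ± 0.25 and 0.91 ± 0.16, with an adjusted p of 0.349 each.

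Across the transcriptome the groups differed little. The median absolute log2 fold change was 0.08, and for 13394 genes, 93.5% of those tested, the 95% interval lay within a 2-fold change in either direction. At an unadjusted p under 0.05 there were 951 genes, 457 higher and 494 lower, where 716 would pass by chance if the libraries were interchangeable. Other splits of the 6 libraries into 3 and 3 gave 179 to 1989 genes, so the excess over 716 cannot be read as an effect of poly-GA. The count of 951 went to 484 without AAV-GFP replicate 2 and to 2861 without AAV-GFP replicate 3. The groups did not overlap for 11.9% of tested genes, against 10% by chance for 3 libraries against 3.

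The libraries also differed in ways that followed the groups only in part or not at all. AAV-GFP replicate 3 had 1 read from the 4 Y-linked genes of the table, where the other 5 libraries had between 2018 and 2270. Genes of intestinal epithelium, a list of 49 measured genes drawn up after the data were seen, had 748, 883 and 1124 reads in the AAV-GFP-GA libraries and 788 in AAV-GFP replicate 3. The same genes had 257 and 242 reads in AAV-GFP replicates 1 and 2. The first principal component of log2 CPM, with 32.5% of the variance, likewise placed AAV-GFP replicates 1 and 2, at 22.2 and 18.02, apart from the other 4 libraries, which lay between -18.3 and -3.99. With a term for these library sets, which compares the 3 AAV-GFP-GA libraries with AAV-GFP replicate 3 alone, the log2 fold changes were 1.51 ± 0.13 for Nes, 1.27 ± 0.15 for Klf4 and 0.81 ± 0.12 for Klf2. The adjusted p-values from edgeR were then 0.00147, 0.0219 and 0.0659, so the call of Klf2 ended. These values rest on AAV-GFP replicate 3, the library that differs from the others in its Y-linked reads, and the labels give no sex. The set with fewer intestinal reads holds libraries of AAV-GFP only, so no comparison within it could be made. All 3 AAV-GFP-GA libraries are in the other set, so the comparison of the groups is largely confounded with that of the sets.

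**Figure D2:**
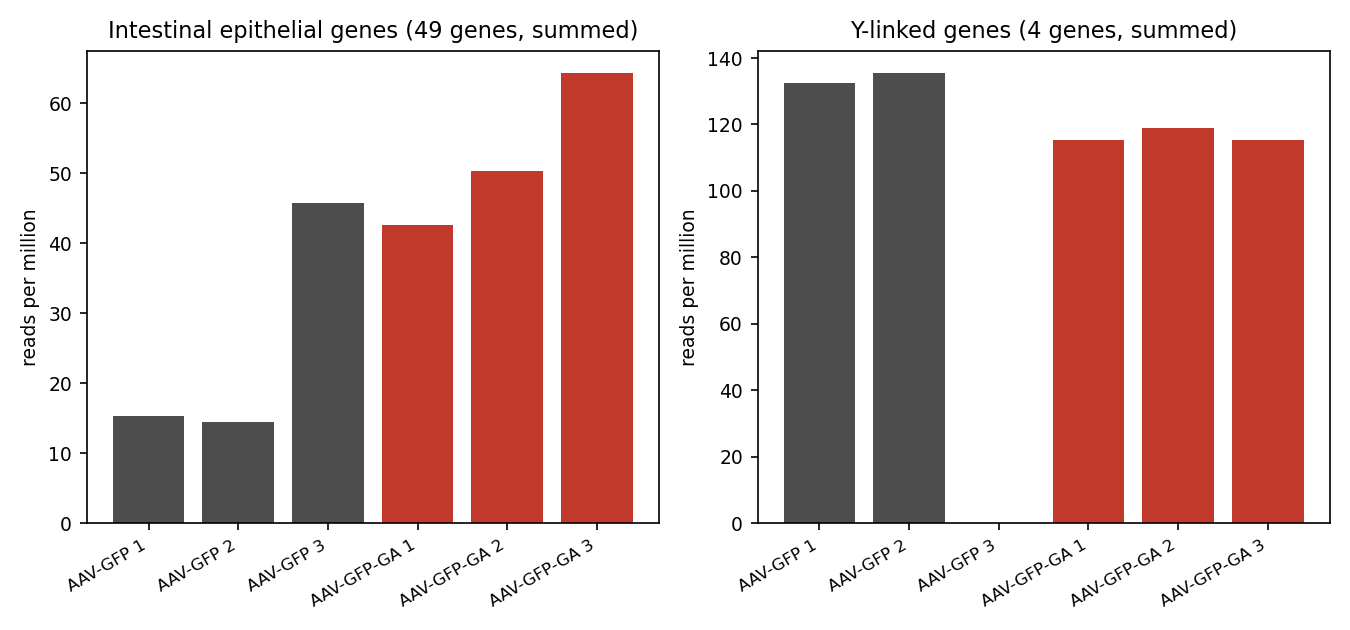
Reads, in CPM, summed over 49 genes of intestinal epithelium (left) and over 4 Y-linked genes (right) in each of the 6 libraries, with AAV-GFP in grey and AAV-GFP-GA in red. Reads of intestinal genes were at 15.3 and 14.4 CPM in AAV-GFP replicates 1 and 2 and between 42.6 and 64.3 CPM in the other 4 libraries, and AAV-GFP replicate 3 had almost no Y-linked reads.

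Transcripts of microglial genes and of the genes that the study's title points to showed no change past the threshold. Transcript levels in whole cortex do not measure protein, inflammasome activation or the clearance of poly-GA. Trem2 (Entrez gene 83433, chromosome 17, 48346401 to 48352276) was at 11.6 ± 1.87 CPM with poly-GA and 11.0 ± 0.492 CPM without (SD, n = 3 per group). Its log2 fold change of 0.07 ± 0.12 had a 95% interval from -0.20 to 0.35, or 0.869-fold to 1.27-fold, and from 0.837-fold to 1.44-fold inside the library set of AAV-GFP replicate 3. Tyrobp, the signalling adaptor of TREM2 (Entrez gene 22177, chromosome 7, 30413782 to 30417582), had a log2 fold change of 0.03 ± 0.13. Cd68, a lysosomal protein of phagocytes (Entrez gene 12514, chromosome 11, 69664213 to 69666170), had 0.06 ± 0.14, and Aif1, which encodes the microglial protein IBA1 (Entrez gene 11629, chromosome 17, 35170986 to 35176083), had -0.21 ± 0.17. The adjusted p by edgeR was 0.920 for Trem2, 0.974 for Tyrobp, 0.946 for Cd68 and 0.798 for Aif1. Inside the library set of AAV-GFP replicate 3 their log2 fold changes were 0.13 ± 0.18, 0.18 ± 0.17, -0.17 ± 0.17 and -0.41 ± 0.22, and none passed. Of the 24 tested genes of disease-associated microglia, 0 passed over all genes and 0 when adjusted over the list alone, and 1, Apoe, had an unadjusted p under 0.05. Apoe, which encodes the lipid carrier apolipoprotein E, was at 1250 ± 40.7 against 1148 ± 35.6 CPM, and Fth1, a subunit of ferritin, at 1647 ± 109 against 1586 ± 205 CPM (SD, n = 3 per group). The median log2 fold change of this list was 0.07 and its camera test had an adjusted p of 0.115. That p was 0.0193 without AAV-GFP-GA replicate 1 and 0.0165 without AAV-GFP-GA replicate 3 (adjusted p = 0.546 and 0.786 with an estimated correlation). Without AAV-GFP-GA replicate 2 the test had a negative sign and an adjusted p of 0.912, the highest of its alternatives. Of 18 genes of homeostatic microglia 0 passed either way, and 4, all higher, had an unadjusted p under 0.05 by edgeR. The list had a median of 0.06 and a camera adjusted p of 0.0527. Inside the library set of AAV-GFP replicate 3 that p was 0.00881 (adjusted p = 0.727 with an estimated correlation). It was 0.00699 without AAV-GFP-GA replicate 1 and 0.00145 without AAV-GFP replicate 2 (adjusted p = 0.504 and 0.748 with an estimated correlation), in a range up to 0.370. Csf1r, a growth factor receptor of microglia, had a log2 fold change of 0.13 ± 0.05.

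Transcripts of the inflammasome were mostly at the lower end of detection in this tissue. Nlrp3, the sensor (Entrez gene 216799, chromosome 11, 59541569 to 59566955), had 9, 13 and 7 reads with poly-GA and 5, 8 and 16 without. Il1b, which encodes interleukin-1β (Entrez gene 16176, chromosome 2, 129364569 to 129371164), had 5, 4 and 4 reads against 5, 5 and 1. Both were below the filter on expression. With no filter on low counts their log2 fold changes were -0.04 ± 0.48 and 0.18 ± 0.68, with 95% intervals from 0.475-fold to 1.98-fold and from 0.414-fold to 3.12-fold, and neither passed. Pycard, which encodes the adaptor ASC (Entrez gene 66824, chromosome 7, 127991373 to 127993867), had 1.33 ± 0.313 against 1.45 ± 0.386 CPM, and Casp1 (Entrez gene 12362, chromosome 9, 5298517 to 5307281) had 2.46 ± 0.441 against 2.74 ± 0.405 CPM (SD, n = 3 per group). Their log2 fold changes were -0.13 ± 0.30 and -0.16 ± 0.22, with adjusted p-values of 0.944 and 0.893 by edgeR, and inside the library set of AAV-GFP replicate 3 they were -0.47 ± 0.37 and 0.05 ± 0.31, which did not pass. Of the 16 tested genes of inflammasome and pyroptosis 0 passed over all genes or when adjusted over the list alone. The list's median log2 fold change was -0.02, its mean was 0.03 and its camera test, with an adjusted p of 0.997, had a negative sign. Its most expressed members, Txnip and Nek7, had log2 fold changes of -0.07 ± 0.13 and -0.03 ± 0.09.

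Interferon-stimulated genes and genes of MHC class I presentation were higher as groups in the camera test, and no single member passed. The median log2 fold change was 0.38 over 26 type I interferon response genes, 25 of them positive, with a camera adjusted p of 2.99e-05 (adjusted p = 0.601 with an estimated correlation). Stat2, a transcription factor of the response, had -0.14 ± 0.09. AAV-GFP-GA replicate 2 carried most of this difference. The mean deviation of the list's genes from their mean over all libraries was 0.71 in that library. It was -0.03 and -0.15 in the other AAV-GFP-GA libraries, and -0.24, -0.32 and 0.03 in the AAV-GFP libraries. Without AAV-GFP-GA replicate 2 the median log2 fold change was 0.05 and the camera adjusted p 0.380, and over all alternatives that p ranged from 2.42e-09 to 0.380. For MHC class I presentation the median was 0.24 over 15 genes, with a camera adjusted p of 0.00154 (adjusted p = 0.601 with an estimated correlation). H2-D1, a class I heavy chain, had 0.33 ± 0.14, and 0.03 ± 0.15 inside the library set of AAV-GFP replicate 3, and B2m, the invariant light chain, had a 95% interval from -0.18 to 0.18. Without AAV-GFP-GA replicate 2 its median was 0.15 and its camera adjusted p 0.105. Inside the library set that includes AAV-GFP replicate 3, the camera adjusted p was 0.332 for the interferon list, with a median of 0.20. It was 0.829 for the MHC class I list, with a median of 0.0075, in a range from 1.81e-04 to 0.829 over all alternatives. Of 6 genes of MHC class II presentation 0 passed either way, with a median of -0.30 and a camera adjusted p of 0.664. Cd74, the invariant chain of class II, was at 5.53 ± 0.452 against 7.30 ± 6.44 CPM, and H2-DMa at 11.7 ± 0.703 against 12.5 ± 1.37 CPM (SD, n = 3 per group). The mean deviation of this list was 1.004 in AAV-GFP replicate 3 and between -0.65 and 0.14 in the other libraries. Against AAV-GFP replicate 3 alone its median log2 fold change was -1.39, and over all alternatives its camera adjusted p ranged up to 0.992. Cd74 was called lower against AAV-GFP replicate 3 alone, with a log2 fold change of -1.41 ± 0.17 that rests on that control library. Without AAV-GFP replicate 2 the camera adjusted p of the list was 0.0172 (adjusted p = 0.748 with an estimated correlation). Of 16 complement genes 0 passed either way, with a median of 0.18 and a camera adjusted p of 0.0734. That p was 0.00540 without AAV-GFP-GA replicate 1, 0.0426 without AAV-GFP-GA replicate 3 and 0.0328 without AAV-GFP replicate 1 (adjusted p = 0.504, 0.794 and 0.710 with an estimated correlation), in a range up to 0.407. The mean deviation of the complement list was 0.26 in AAV-GFP-GA replicate 2 and -0.06 in each of the other AAV-GFP-GA libraries. It was 0.02, -0.16 and 0.004 in AAV-GFP replicates 1, 2 and 3. C1qa and C1qb, chains of the initiating complex, had log2 fold changes of 0.17 ± 0.09 and 0.26 ± 0.11. These were 0.06 ± 0.11 and 0.07 ± 0.13 inside the library set of AAV-GFP replicate 3, where the list had a median of 0.13 and a camera adjusted p of 0.332.

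Transcripts of clearance pathways moved little. The lysosome list of 29 genes had a median log2 fold change of 0.06, with 24 members positive and a camera adjusted p of 0.0139 (adjusted p = 0.601 with an estimated correlation). Psap, the precursor of the saposins, had 0.10 ± 0.05, and Ctsb, a lysosomal protease, 0.07 ± 0.07. Phagocytic and pattern receptors had a median of 0.11 over 24 genes, 16 of them positive, with a camera adjusted p of 0.0407 (adjusted p = 0.601 with an estimated correlation). The phagocytic receptor kinases Axl and Mertk had 0.09 ± 0.06 and -0.03 ± 0.09. The 19 autophagy genes had a median of -0.02 and a camera adjusted p of 0.732. Sqstm1, the autophagy receptor p62, had 0.11 ± 0.06 and Gabarapl1 -0.03 ± 0.06. The 31 proteasome genes had a median of -0.01 and a camera adjusted p of 0.579, with Psmd2 at -0.03 ± 0.06 and Psmd1 at -0.01 ± 0.05. In each of these 4 lists 0 members passed over all genes or when adjusted over the list alone. The camera call of the lysosome list was lost without AAV-GFP-GA replicate 2, where its adjusted p was 0.340, and with the library set term, where it was 0.437, in a range from 0.00193 to 0.437. That of the receptors was lost without AAV-GFP-GA replicate 2, AAV-GFP-GA replicate 3 or AAV-GFP replicate 3, with adjusted p-values of 0.129, 0.0868 and 0.354, with either other filter on low counts (0.0529 with none, 0.0536 with the stricter one) and with sample weights (0.209), in a range from 0.0172 to 0.355.

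Astrocyte genes did not pass over all genes. Gfap, the intermediate filament of reactive astrocytes (Entrez gene 14580, chromosome 11, 102887336 to 102897200), was at 233 ± 79.7 CPM with poly-GA and 172 ± 29.4 CPM without (SD, n = 3 per group). Its log2 fold change was 0.43 ± 0.20, with a 95% interval from -0.01 to 0.88 and an adjusted p of 0.746 by edgeR. The reads were 3693, 5694 and 2877 against 3264, 3054 and 2411, so that the groups overlapped. Inside the library set of AAV-GFP replicate 3 the log2 fold change was 0.74 ± 0.27, which did not pass. Vim, the filament vimentin, had 0.26 ± 0.09. Of 17 tested genes of reactive astrocytes, 1 rose when adjusted over the list alone, Osmr, a receptor subunit for oncostatin M, with a log2 fold change of 0.66 ± 0.17. Its adjusted p was 0.0402 over the list and 0.742 over all genes, and inside the library set it had 0.85 ± 0.24 and no longer passed over the list (adjusted p 0.0632). The list had a median of 0.06 and a camera adjusted p of 0.0527, which was 0.0112 inside the library set of AAV-GFP replicate 3 (adjusted p = 0.727 with an estimated correlation). It was 0.00540, 0.0426 and 0.00417 without AAV-GFP-GA replicate 1, AAV-GFP-GA replicate 3 and AAV-GFP replicate 1 (adjusted p = 0.504, 0.794 and 0.664 with an estimated correlation), in a range up to 0.425. Over 15 alternatives the camera test called this list higher in 5, and none of these calls held with an estimated correlation. The mean deviation of the list was 0.22 in AAV-GFP-GA replicate 2 and -0.03 and -0.01 in the other AAV-GFP-GA libraries. It was 0.09, -0.09 and -0.18 in AAV-GFP replicates 1, 2 and 3. Of 16 genes of homeostatic astrocytes 0 passed either way, with a median of 0.02 and a camera adjusted p of 0.403, which was 0.0267 without AAV-GFP-GA replicate 1, in a range up to 0.701 (adjusted p = 0.504 with an estimated correlation). Slc1a2, the main glutamate transporter, had -0.04 ± 0.07, and Glul, glutamine synthetase, -0.06 ± 0.06.

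Vessel genes were higher as a group. The 14 endothelial genes had a median log2 fold change of 0.23, 13 of them positive, and a camera adjusted p of 3.91e-06 (adjusted p = 0.601 with an estimated correlation). None passed over all genes, and 3 rose when adjusted over the list alone: Flt1, the glucose transporter Slc2a1 and the efflux pump Abcb1a. Slc2a1 was at 153 ± 20.5 against 110 ± 17.99 CPM (SD, n = 3 per group), and Abcb1a had a log2 fold change of 0.32 ± 0.10. The log2 fold change inside the library set of AAV-GFP replicate 3 was 0.42 ± 0.10 for Flt1, 0.24 ± 0.12 for Slc2a1 and 0.21 ± 0.12 for Abcb1a, so that over the list alone Flt1 still passed (adjusted p 0.0326) and the other genes did not (0.406 and 0.417). Pltp, a lipid transfer protein, had 0.27 ± 0.14, and 0.04 ± 0.16 inside that set. AAV-GFP-GA replicate 2 stood apart in this list, with a mean deviation of 0.27. The other AAV-GFP-GA libraries were at 0.02 and 0.04, near AAV-GFP replicate 3 at 0.01, and AAV-GFP replicates 1 and 2 were at -0.10 and -0.24. The endothelial call held with any 1 library left out, and inside the library set of AAV-GFP replicate 3 its median was 0.14 and its camera adjusted p 0.0999, in a range from 6.47e-09 to 0.0999. The 11 genes of mural cells, which wrap vessels, had a median of 0.17, 9 of them positive, and a camera adjusted p of 0.00426 (adjusted p = 0.601 with an estimated correlation). Vtn had 0.25 ± 0.09 and Rgs5 0.05 ± 0.08. The mural call was lost without AAV-GFP-GA replicate 2 or AAV-GFP replicate 3, with adjusted p-values of 0.170 and 0.0668, in a range from 7.66e-06 to 0.170. In the mural list 0 members passed over all genes or when adjusted over the list alone.

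Neuronal genes were close between the groups. Synapse genes had a median log2 fold change of 0.02 over 28 genes, 18 of them positive, and a camera adjusted p of 0.0344 (adjusted p = 0.601 with an estimated correlation). Snap25 and Syt1, proteins of transmitter release, had 0.01 ± 0.05 and -0.02 ± 0.05. The synapse call was lost without AAV-GFP-GA replicate 3 or AAV-GFP replicate 3, with adjusted p-values of 0.0768 and 0.358, and with sample weights (0.215), in a range from 0.00126 to 0.370. The 18 genes of excitatory neurons had a median of 0.03 and a mean of -0.01, and their camera test, with an adjusted p of 0.525, had a positive sign. Camk2a and Slc17a7 had 0.08 ± 0.05 and 0.12 ± 0.06. The 17 genes of inhibitory neurons had a median of 0.01 with a mean just below 0, a positive camera sign and a camera adjusted p of 0.732, and Gad1 and Gad2, which make GABA, had -0.04 ± 0.06 and -0.17 ± 0.15. The 18 immediate early genes, which follow neuronal activity, had a median of -0.08 and a camera adjusted p of 0.114. Arc was at 351 ± 35.3 against 464 ± 124 CPM and Egr1 at 581 ± 29.2 against 605 ± 94.3 CPM (SD, n = 3 per group). The direction of this list depended on the control libraries. Its median was -0.20 without AAV-GFP replicate 3 (camera adjusted p = 1.97e-05) and 0.20 against AAV-GFP replicate 3 alone. Over 15 alternatives the camera test called the list lower in 4 and higher in 1, and its adjusted p ranged up to 0.218. None of these calls held with an estimated correlation (adjusted p = 0.887 without AAV-GFP replicate 3). Of the 20 genes of amyotrophic lateral sclerosis and frontotemporal dementia 0 passed either way, with a median of -0.04 and a camera adjusted p of 0.162, and Kif5a and Mapt had 0.07 ± 0.05 and 0.01 ± 0.05. In the other lists of this paragraph, too, 0 members passed over all genes or when adjusted over the list alone.

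Heat shock genes were lower as a group. The 15 genes had a median log2 fold change of -0.21, 2 of them positive, and a camera adjusted p of 1.77e-04 (adjusted p = 0.601 with an estimated correlation). No member passed over all genes or when adjusted over the list alone, and 6 had an unadjusted p under 0.05. Hsp90aa1, a cytosolic chaperone, had -0.14 ± 0.06, and Hspa8 -0.03 ± 0.04. The mean deviation of this list was 0.39 and 0.19 in AAV-GFP replicates 1 and 2, -0.23 in AAV-GFP replicate 3 and between -0.16 and -0.07 in the AAV-GFP-GA libraries, so that it followed the library sets. Inside the set of AAV-GFP replicate 3 the direction turned, with a median of 0.077 and a camera adjusted p of 0.0345, in a range from 4.21e-10 to 0.0447 over all alternatives (adjusted p = 0.727 with an estimated correlation). The unfolded protein response list had a median of -0.01 and a mean of 0.04 over 22 genes, and its camera test, with an adjusted p of 0.688, had a negative sign. In it 0 members passed over all genes and 1, Atf3, rose when adjusted over the list alone, with an adjusted p of 0.00657, and 0.00991 inside the library set. The chaperones Hsp90b1 and Calr had -0.01 ± 0.06 and -0.04 ± 0.06.

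**Figure D3:**
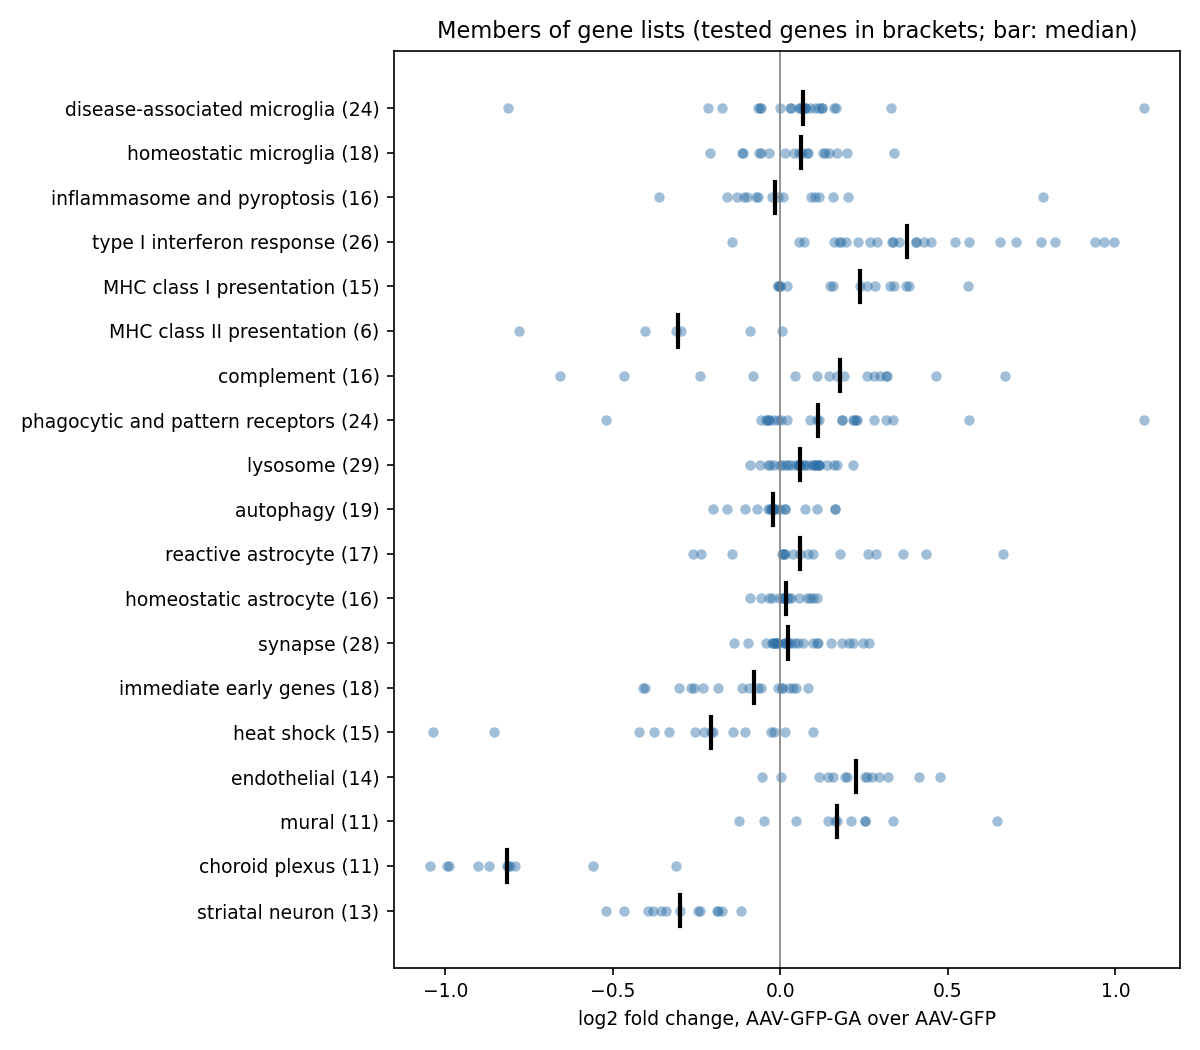
Log2 fold change, AAV-GFP-GA over AAV-GFP, of the tested members (points) of 19 gene lists fixed before the data were examined, with the median of each list as a bar and the number of tested members in brackets. The medians of most lists lie near 0, with the endothelial list at 0.23, the interferon list at 0.38, the heat shock list at -0.21 and the choroid plexus list at -0.82.

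Over the 37 lists together, 575 genes were tested, and by edgeR 0 passed over all genes while 51 had an unadjusted p under 0.05, 30 higher and 21 lower. Of the list genes DESeq2 called 3, Flt1, Slc2a1 and Atf3. The camera test with its preset correlation called 11 lists, 8 higher and 3 lower. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.601 and 1 list had an unadjusted p under 0.05. The fry test called none in 1 direction, with a smallest adjusted p of 0.813 and 1 list at an unadjusted p under 0.05, and none in its mixed form, with a smallest adjusted p of 0.383 and 2 lists at an unadjusted p under 0.05. With the term for the library sets 1 list, the sex-linked genes, passed camera with the estimated correlation and fry.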

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

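The terms for the library set and for the Y-linked reads were chosen after the data were seen, and the other alternatives were planned. Nes and Klf4 passed in all 15 alternatives, with log2 fold changes from 1.15 to 1.51 and from 1.09 to 1.27, and Klf2 passed in 10, with 0.81 to 0.96. The count of 3 changed genes, all higher, was also found with limma-voom, DESeq2 size factors and the stricter filter. It was 4 with no filter and with sample weights, and 10 (9 higher, 1 lower) with DESeq2. With the library set term it was 9 (6 higher, 3 lower; 5 named genes called), of which 4 were Y-linked genes, and with the Y-linked term 75 (38 higher, 37 lower). Leaving out 1 library gave 2 to 72 changed genes, 2 to 38 higher and 0 to 34 lower, 4 to 18 called lists and 2 to 4 called named genes. The highest counts of genes came without AAV-GFP replicate 3, and the Y-linked term removes the same library by its construction. With an estimated correlation, and with fry, 1 list passed with the library set term, the sex-linked list. Calls of lists with the preset correlation, 11 as reported, fell to 4 without AAV-GFP-GA replicate 2 and went to 18 without AAV-GFP-GA replicate 1. For the other changes the cause was not tested. The values showed no sign that replicate numbers pair the libraries. Deviations of libraries with the same number had correlations of 0.07, -0.06 and 0.02, and no library correlated best with its own number. With 3 libraries per group and labels that do not say, pairing cannot be excluded. With the replicate block 2 genes were called, 2 higher and 0 lower, 13 lists were called, and Klf2 had 0.90 with an adjusted p of 0.0540.

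With the library set term 4 lists turned direction in the camera test: MHC class I presentation (median log2 fold change 0.0075), immediate early genes (0.20), hippocampal neuron (0.84) and heat shock (0.077). The sex-linked list turned to -0.23 with the Y-linked term, and to -0.23 without AAV-GFP replicate 3, where its range over libraries left out was -0.23 to 0.80. The cause of these turns was not tested, except that the sex-linked list turns because AAV-GFP replicate 3, with 1 Y-linked read, leaves the comparison. Among the remaining values of single lists 31 gained and 31 lost a camera call without turning, and 487 stayed on the same side, 43 of them with another sign and no call in either fit. Among values of named genes 6 gained and 5 lost a call and 1234 stayed, 113 of them with another sign and no call. At 16748754 to 17576017 reads per library the filter left out genes with a few reads. Without it the 95% intervals of Nlrp3 and Il1b still reached from 0.475-fold to 1.98-fold and from 0.414-fold to 3.12-fold.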

Other observations

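The choroid plexus list, genes of the epithelium that makes cerebrospinal fluid, was lower as a group and varied between single libraries. Its 11 genes had a median log2 fold change of -0.82, all negative, and a camera adjusted p of 1.70e-04 (adjusted p = 0.601 with an estimated correlation). Ttr, the thyroid hormone carrier transthyretin, was at 310 ± 247 against 580 ± 416 CPM and Kl, the hormone coreceptor klotho, at 19.0 ± 11.5 against 33.4 ± 17.8 CPM (SD, n = 3 per group). The mean deviation of the list was -1.98 in AAV-GFP-GA replicate 3 and 1.35 in AAV-GFP replicate 1, and without AAV-GFP-GA replicate 3 the camera adjusted p was 0.218, in a range from 1.45e-10 to 0.218 over all alternatives. Striatal neuron genes, markers of the tissue below the cortex, had a median of -0.30 over 13 genes, all negative, and a camera adjusted p of 0.0371 (adjusted p = 0.845 with an estimated correlation). Penk and Ppp1r1b had log2 fold changes of -0.34 ± 0.23 and -0.12 ± 0.21. That list's mean deviation was -0.60 in AAV-GFP replicate 1 and 0.50 in AAV-GFP replicate 2, so libraries of 1 group differed by more than the groups did. Its call was lost without AAV-GFP-GA replicate 1 or 2 or AAV-GFP replicate 2 or 3, with camera adjusted p-values of 0.0654, 0.244, 0.793 and 0.833, and with sample weights (0.625), in a range from 2.83e-29 to 0.846. Hippocampal neuron genes had a median of -0.10 and a camera adjusted p of 0.403, with Wfs1 at -0.11 ± 0.09 and Nnat at -0.07 ± 0.14. Their mean deviation was -1.04 in AAV-GFP-GA replicate 3 and -0.88 in AAV-GFP replicate 3, against 0.28 to 0.80 in the other 4 libraries. Inside the library set of AAV-GFP replicate 3 this list had a median of 0.84 (camera adjusted p 0.000115, in a range up to 0.867), and without AAV-GFP replicate 3 it had -0.34 (0.00372) and without AAV-GFP-GA replicate 1 -0.22 (0.0311). None of these calls held (adjusted p = 0.727, 0.887 and 0.557 with an estimated correlation). Thalamic and habenular genes had a median of 0.23 and a camera adjusted p of 0.115, with Rora at 0.09 ± 0.06 and Calb2 at -0.05 ± 0.15. Inside the library set the thalamic median was 0.39 (camera adjusted p 0.000314, in a range up to 0.901), and without AAV-GFP replicate 2 it was 0.17 (0.00145). Neither call held (adjusted p = 0.538 and 0.748 with an estimated correlation).

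Most other lists showed no call with all 6 libraries. Oligodendrocyte and myelin genes had a median of 0.01 with a negative mean and a negative camera sign (adjusted p 0.807), with Mbp at 0.07 ± 0.05. Oligodendrocyte precursors had a median of 0.01 (camera adjusted p 0.492), with Olig1 at 0.09 ± 0.08 and Bcas1 at 0.02 ± 0.09. Border macrophages had 0.16 (0.579 by camera, adjusted), with Mrc1 at 0.28 ± 0.22 and Stab1 at 0.16 ± 0.12. Leptomeningeal fibroblasts had 0.06 (camera adjusted p 0.325), with Igf2 at -0.17 ± 0.19 and Igfbp2 at 0.12 ± 0.20. Their median was 0.13 without AAV-GFP-GA replicate 1 (camera adjusted p 0.0267) and 0.23 without AAV-GFP replicate 1 (0.000323, in a range up to 0.905), and neither call held (adjusted p = 0.546 and 0.664 with an estimated correlation). It was -0.07 without AAV-GFP replicate 2. Ependymal genes had a median of 0.11 with a negative mean of -0.01, a negative camera sign and a positive fry sign (camera adjusted p 0.982), with Foxj1 at -0.13 ± 0.19 and Rsph1 at -0.07 ± 0.17. Red blood cell genes had 0.03 (camera adjusted p 0.579), with Hbb-bs at 0.03 ± 0.27, and inside the library set of AAV-GFP replicate 3 they had 0.66 (4.49e-06, in a range up to 0.849) and without AAV-GFP replicate 1 0.47 (9.60e-05). Neither call held (adjusted p = 0.538 and 0.664 with an estimated correlation). Cytokines and chemokines had 0.08 (camera adjusted p 0.324), with Cx3cl1 at 0.05 ± 0.05 and Il33 at -0.03 ± 0.07. Genes of the p53 response had -0.05 (camera adjusted p 0.115), with Plk2 and Ccng1 at -0.01 ± 0.05 and -0.01 ± 0.07. Proliferation genes had 0.01 (camera adjusted p 0.710), with Pcna at 0.03 ± 0.09 and Stmn1 at 0.00056 ± 0.062. Nuclear genes of the respiratory chain had -0.03 (camera adjusted p 0.115), with Atp5b at 0.02 ± 0.05 and Atp5a1 at 0.04 ± 0.05. That p was 0.000470 without AAV-GFP-GA replicate 1 and 0.0456 without AAV-GFP replicate 1, in a range up to 0.679 (adjusted p = 0.504 and 0.768 with an estimated correlation). The 4 sex-linked genes had a median of 0.36 and a camera adjusted p of 0.0407 (adjusted p = 0.601 with an estimated correlation), with Ddx3y at 0.41 ± 0.74 and Eif2s3y at 0.27 ± 0.71, and AAV-GFP replicate 3 had a single Y-linked read. Without that library the sex-linked list had a median of -0.23 and a camera adjusted p of 0.0385 (adjusted p = 0.887 with an estimated correlation). The call upward was also lost without AAV-GFP-GA replicate 2 or 3 (0.105 and 0.0768), with no filter on low counts (0.0529), with sample weights (0.323) and with the Y-linked term (0.119), in a range from 4.57e-39 to 0.323. The lists of T and NK cells, of B and plasma cells and of monocytes and neutrophils had too few tested members, with 329 to 338 against 218 to 495 reads, 20 to 32 against 15 to 24 reads, and 474 to 596 against 481 to 557 reads per library. Most of the reads of T and NK cells came from Cd4, with 158 to 423 per library, and most of those of monocytes and neutrophils from Vcan, also in the list of oligodendrocyte precursors, and Csf3r, with 316 to 440 and 78 to 144. Cd3e, Cd3d, Cd8a, Ly6g, S100a8 and Ccr2 had 0 to 9 reads per library, and these genes were picked after their reads were seen. The list of mitochondrially encoded genes was not analysed here.

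The tests in the next 3 paragraphs were chosen only after the results they bear on were seen, and each explanation in them is a hypothesis. Reads of intestinal epithelial genes were present in all 3 AAV-GFP-GA libraries and in AAV-GFP replicate 3. Apoa1 had 44, 42 and 77 reads with poly-GA and 0, 1 and 50 without, and all 48 detected members of the list had a higher share in these 4 libraries, although 22 and 21 members also had reads in AAV-GFP replicates 1 and 2. Expression of poly-GA is argued against as the cause, as far as the label of AAV-GFP replicate 3 holds, since that library is labelled as carrying none and had 3.07 times (95% exact interval for counting error only, 2.74 to 3.44) the share of reads from the list that AAV-GFP replicates 1 and 2 had. Intestinal RNA or reads carried into 4 of the 6 libraries is a candidate explanation. Among members not inspected before the test 11 of 11, or 100%, were higher in the 4 libraries. These genes were measured in the same 6 libraries and can move together, so their number measures no replication. Any cause that moves intestinal genes together would give the same count. Whether such a carry-over happened at dissection, library preparation or sequencing remains open. A list of anterior pituitary genes had 287 to 445 reads in the 4 libraries and 70 and 91 in the other pair. Prl (41 to 158 reads against 0 and 0) and Gh (63 to 227 against 0 and 5) followed these sets. Tshb (44 to 76 against 56 and 63) and Lhb (1 to 9 against 8 and 8) did not. Pomc had 113 reads in AAV-GFP replicate 3 and 6 to 22 in the other libraries.

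Without AAV-GFP replicate 3 there were 72 called genes, 11 of them in the intestinal or pituitary lists and 6, all lower, in the heat shock list. Expression of poly-GA alone and the library set cannot be told apart for these genes, because AAV-GFP replicates 1 and 2, the remaining controls, are both outside the set of the AAV-GFP-GA libraries and only 1 control library is inside it. Against that control the 69 genes beyond Nes, Klf4 and Klf2 had a median signed difference of 0.00155 on the log2 scale, where it was 0.41 against AAV-GFP replicates 1 and 2. The 95% bootstrap interval of the former, -0.035 to 0.047, was drawn over genes and does not measure the spread between libraries. AAV-GFP replicate 3 itself differed from AAV-GFP replicates 1 and 2 by a median of 0.404 in the same direction, a value that shares the controls on which the genes were selected and so decides nothing. Sex of the animals is argued against as a source of these calls, since the 5 libraries compared all had at least 2018 Y-linked reads.

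For Nes, Klf4 and Klf2, higher with poly-GA, the biological explanation the design gives, expression of poly-GA, stays open. An even increase of all vessel tissue in the AAV-GFP-GA samples is argued against as the whole cause. The endothelial list had a median log2 fold change of 0.226, and 0.137 to 0.280 with any 1 library left out, below the lowest lower bound of the 3 genes, 0.699. Its 95% bootstrap interval, 0.149 to 0.295, was drawn over its 14 genes and does not measure the spread between libraries. The 3 genes were the only ones past the threshold in these same data, so their lower bounds may lie too high. A list median also cannot speak to a part of the vessels that is rich in these genes. A general immediate early response at tissue collection stays open. With all 6 libraries the immediate early list did not rise with the 3 genes, with a median of -0.0799 (95% bootstrap interval over its genes, -0.230 to 0.00417). That median was -0.20 without AAV-GFP replicate 3 and positive against AAV-GFP replicate 3 alone, so its sign depended on the controls. As its genes follow neuronal activity, the list cannot decide on an early response in other cells. With a term for the library set the log2 fold change was 1.51 for Nes and 1.27 for Klf4. AAV-GFP replicate 3 had 146 reads of Nes and 141 of Klf4, near AAV-GFP replicates 1 and 2 (198 and 165, 157 and 141). The AAV-GFP-GA libraries had 420 to 424 and 316 to 387. This comparison rests on 1 control library, which also differs in its Y-linked reads, so it cannot exclude the set as a cause. For Klf2 the log2 fold change went from 0.90 ± 0.09 to 0.810 ± 0.12 (SE, 95% interval 0.540 to 1.08). The smaller log2 fold change and the wider error ended its call, so the set stays open for Klf2 too. Its adjusted p ranged from 1.28e-08 to 0.0718 over its alternatives.

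The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3 genes and the highest of the other splits 2, so 1 split gave as many. For lists called by camera with the preset correlation the real split gave 11 and the highest other 17, and 6 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split had 951 genes. The 2 splits that set AAV-GFP replicates 1 and 2 with AAV-GFP-GA replicate 3 or 2 apart from the rest had 1989 and 1700, which points to a structure of the samples along the library sets, and the split that set them apart with AAV-GFP-GA replicate 1 had 921.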
